A study of Mus musculus with 6 samples.

How the data were processed

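Liver RNA of 6 male ICR mice was sequenced, 3 given 1000 mg/kg sulfasalazine and 3 given vehicle, each library being a separate sample per the labels. Per the labels' protocols, total RNA with a RIN above 7.0 was depleted of ribosomal RNA and made into cDNA libraries. The deposited table gives FPKM (fragments scaled to transcript length and to the mapped fragments of the library) per locus, per the file headers. The submitters' processing notes name cutadapt, FastQC, Bowtie2, StringTie and the build GRCm38.p5, with no versions; the annotation release is not given in the sources used here. Most locus names are of the kind StringTie gives to merged assembled loci.

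The table holds 42612 loci, of which 24822 carry an Ensembl transcript and 17790 do not. Transcripts were matched to GENCODE M21 on GRCm38 for gene names and coordinates, and 24750 loci matched. Of the tested loci, 562 pool transcripts of more than 1 gene, so their FPKM cannot be given to a single gene. Depth is unknown, since FPKM keeps no total, and no counting interval can be given. An exact 0 can be a failed estimate: 47 of 3616 annotated loci with a median FPKM above 5 were listed at 0 in at least 1 library, and 95.7% of these were single-exon genes against 4.51% of the others. For such loci each library's value is given. Loci without an annotated transcript held 11.0% to 25.3% of the FPKM per library.

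Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, over the 11969 loci with at least 1 FPKM in at least 3 libraries. Fold changes are on that scale, which understates the change of low genes. Lists of genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Some genes stand on several lists, so the called lists are not separate findings. Of 39 lists, 35 had at least 3 tested members; the lymphocyte, neutrophil, pancreas and adipose, and mitochondrial lists did not, and mitochondrial transcripts were not analysed here. Camera called 15 lists, 10 higher and 5 lower; with an estimated correlation 0 were called, and fry called 1.

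The design, lists, rule for named genes and all but 4 kinds of alternative were set before the data were examined; those 4 are named in the closing section. The rule takes up to 10 genes per direction with non-overlapping groups and a mean of at least 2 FPKM in a group, those past the threshold first and then those with the smallest unadjusted p. It adds up to 4 members of each called list by smallest p, the 2 most abundant members of each list that did not pass, and 13 genes named in advance. A gene given outside this rule was chosen after its values were seen, as were Saa1, Lyz2 and the genes of single mice in the closing section. Alternatives changed the pseudocount, filter, scaling, variance model and libraries used, or added the replicate number as a block. The procedure was tested on simulated data with the 11969 loci's means and spreads and 200 changed loci per run over 10 runs: limma recovered 44.8% of loci changed by 1 on the log2 scale and 84.6% of those changed by 4, with 5.34% false calls. Camera called a list with each member shifted by 1 on the log2 scale in 10 of 10 runs. The simulated loci varied independently, whereas members of a real list may vary together, and most called lists had smaller medians. With 200 changed loci the adjusted threshold is also easier to pass than where few loci change. These rates therefore do not carry over to the loci and lists reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.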

Results

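The study measured liver RNA of male ICR mice, an outbred stock, after 4 weeks of sulfasalazine by oral gavage. Sulfasalazine is an anti-inflammatory drug that gut bacteria split into sulfapyridine and 5-aminosalicylic acid. Per the series' title, the question was which transcripts change in the liver injury that the drug causes in mice. The files hold 6 libraries: 3 from mice given 1000 mg/kg and 3 from mice given the 0.1% DMSO vehicle. The doses of 250 and 500 mg/kg that the labels also name were not analysed here. The table gives FPKM, so the number of reads behind each library is unknown. FPKM summed to between 224434 and 260047 per library, and 12391 to 15903 loci reached 1 FPKM. Pearson correlations across the 11969 tested loci were 0.901 to 0.919 within groups and 0.896 to 0.914 between groups, so the groups did not stand apart over these loci.

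In the livers of the treated mice, 1 annotated gene rose past the threshold. Cyp2c55, a cytochrome P450 known to respond to the nuclear receptors CAR and PXR, rose from 0.772 ± 0.198 to 21.3 ± 4.82 FPKM (SD, n = 3 each). Its log2 fold change was 3.64 with an SE of 0.19 on the log2(FPKM + 1) scale (limma, adjusted p = 0.012), and it was higher in 3 of 3 treated mice. The annotation places Cyp2c55 on chromosome 19 from 39007019 to 39042693 in GRCm38, as a protein-coding gene. An assembled locus that the table labels Bcl2l2 also passed (limma, adjusted p = 0.0284). It was listed at 0, 0 and 0.997 FPKM in the control mice and at 22.6, 24.7 and 22.8 in the treated mice, and it carries no annotated transcript. These 2 loci were all that passed among 11969 tested by limma; 0 loci fell, and 899 had an unadjusted p under 0.05 where chance gives 598. The Cyp2c55 call was lost without control mouse 1, without sulfasalazine mouse 3, with no filter and with the replicate number as a block. Its adjusted p by limma lay between 0.0160 and 0.0631 over the 6 fits that each leave out a mouse and keep the tested loci. With the filter applied again, Cyp2c55 was not tested without any 1 of the treated mice, since it passed 1 FPKM in those 3 libraries alone. The Bcl2l2 locus kept its call in 1 of those fits, without control mouse 3 (limma, adjusted p between 0.00165 and 0.109).

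**Figure D1:**
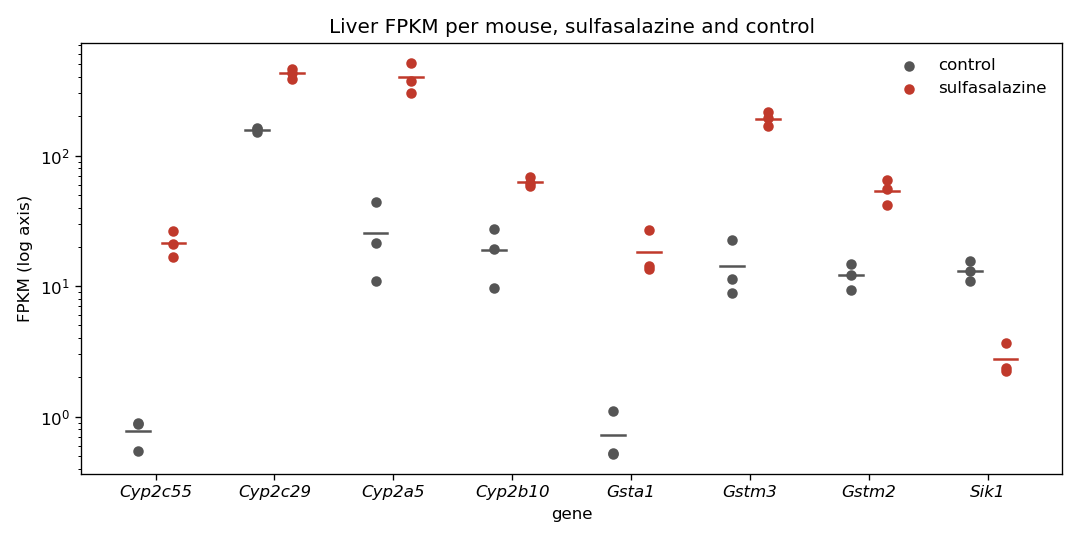
FPKM on a log axis for 8 genes, with 1 point per mouse (grey control, red sulfasalazine, n = 3 each) and a line at each group's mean. The treated mice lie above the control mice for all but Sik1, where they lie below; Cyp2c55 has group means of 0.772 and 21.3 FPKM and is the 1 gene shown that passed the test.

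The list of CAR and PXR targets, fixed before the data were examined, was higher as a group. Of its 19 tested members 1 rose, 18 did not pass, and 9 passed upward when adjusted over the list alone. The median log2 fold change was 1.33 (limma's camera, adjusted p = 1.95e-11), with an adjusted p of 0.158 with an estimated correlation. Cyp2a5, a coumarin hydroxylase, had 25.4 ± 17.0 FPKM in control and 397 ± 109 in treated livers (SD, n = 3 each; limma, adjusted p = 0.107). Cyp2c29 had 158 ± 4.74 and 427 ± 37.1 FPKM, at a locus that also holds the pseudogene Cyp2c53-ps (limma, adjusted p = 0.0524). Cyp2b10, the usual CAR marker, had 18.8 ± 8.74 and 62.8 ± 5.30 FPKM (limma, adjusted p = 0.281). Cyp3a11, the usual PXR marker, had 966 ± 262 and 1309 ± 436 FPKM, a difference within the spread between mice. Many of these genes have close paralogs, between which the authors' assembly could divide reads.

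Several glutathione transferases went the same way, but 11 of 36 tested phase II genes had negative fold changes. Of the 2 most abundant phase II members, the locus pooling Gstp1 and Gstp2 had 474 ± 93.9 FPKM in control and 344 ± 109 in treated livers. The other, Mgst1, had 522 ± 36.2 and 623 ± 66.4 FPKM. Gstm3 had 14.2 ± 7.26 FPKM in control and 192 ± 22.8 in treated livers, a log2 fold change of 3.77 with an SE of 0.33 (limma, adjusted p = 0.0524). Gsta1 had 0.721 ± 0.342 and 18.2 ± 7.52 FPKM (limma, adjusted p = 0.0524), and Gstm2 had 12.1 ± 2.70 and 53.9 ± 11.6 FPKM. The NRF2 list, named for the regulator of antioxidant genes, shares Gsta1, Gsta2 and Gstm3, among others, with the phase II list. In the NRF2 list 0 of 22 tested members passed and 8 passed upward when adjusted over the list alone. The list's median was 0.37 (limma's camera, adjusted p = 2.75e-08; adjusted p = 0.448 with an estimated correlation). Its classical members were uneven: Nqo1 had 1.32 ± 0.849 and 3.09 ± 0.845 FPKM, while Hmox1 had 28.7 ± 14.3 and 18.8 ± 3.50. In the phase II list 0 of 36 members passed and 4 passed upward when adjusted over the list alone; the median was 0.23 (limma's camera, adjusted p = 0.000107; adjusted p = 0.495 with an estimated correlation).

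Of 3 lists of lipid genes, cholesterol biosynthesis and fatty acid oxidation were called and lipogenesis was not, with a median of 0.13 (limma's camera, adjusted p = 0.218). Without sulfasalazine mouse 1 lipogenesis was called higher, with a median of 0.31 (limma's camera, adjusted p = 0.0204). It was not called in the other fits that leave out a mouse. All 23 tested cholesterol biosynthesis genes had positive fold changes with a median of 0.29, and 0 passed alone or when adjusted over the list alone (limma's camera, adjusted p = 2.81e-05; adjusted p = 0.615 with an estimated correlation). The cholesterol list's means per mouse, relative to the control mean, overlapped between groups, with 0.25 in control mouse 2 and 0.14 in sulfasalazine mouse 1. Hmgcs1, the cytosolic HMG-CoA synthase, had 14.2 ± 5.70 FPKM in control and 28.5 ± 9.39 in treated livers. Of 39 tested genes of the PPARalpha and fatty acid oxidation list 34 were positive, with a median of 0.30, 0 passing and 1 passing when adjusted over the list alone (limma's camera, adjusted p = 3.83e-06; adjusted p = 0.615 with an estimated correlation). Aldh3a2, a fatty aldehyde dehydrogenase, had 11.2 ± 0.765 and 26.1 ± 7.06 FPKM. Control mouse 1 stood apart from the other controls here: Cyp4a10 was at 232 FPKM in it and at 38.6 and 23.3 in the others. The PPARalpha list's mean, relative to the control mean, was 0.45 in control mouse 1, above the 0.12 of sulfasalazine mouse 3. The 5 lists described so far as called were called in each of the 6 fits that leave out a mouse, but medians moved. They lay between 0.15 (without control mouse 1) and 0.44 (without sulfasalazine mouse 1) for cholesterol genes, between 0.16 (without sulfasalazine mouse 2) and 0.47 (without sulfasalazine mouse 3) for PPARalpha genes, and between 0.13 (without control mouse 3) and 0.33 (without sulfasalazine mouse 1) for phase II genes.

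Of the 5 lower lists, 3 held matrix, acute phase and male-biased genes, and the other 2 are given further below. In each of the 5, 0 genes passed, also when adjusted over the list alone. The 16 tested stellate cell and matrix genes had a median of -0.40 (limma's camera, adjusted p = 0.000142; adjusted p = 0.615 with an estimated correlation). Fibronectin, Fn1, had 200 ± 11.6 FPKM in control and 145 ± 3.88 in treated livers, and decorin, Dcn, had 44.1 ± 3.35 and 35.1 ± 1.46. The 23 acute phase genes had a median of -0.32 (limma's camera, adjusted p = 0.00324; adjusted p = 0.615 with an estimated correlation). Lrg1 was at 210, 13.8 and 268 FPKM in the control mice and at 2.01, 3.60 and 27.8 in the treated mice. Control mouse 3 had the highest Saa1, at 113 FPKM against 20.7 or less in the other 5 mice, and the highest macrophage marker Lyz2, at 84.5 against 16.8 or less. Without that mouse neither list was called, and without sulfasalazine mouse 2 acute phase genes were not (limma's camera, adjusted p up to 0.128 for matrix and up to 0.219 for acute phase genes). The medians without control mouse 3 were -0.05 for matrix and -0.19 for acute phase genes, and the matrix median was -0.22 without sulfasalazine mouse 2. Over all 6 mice the Kupffer cell and macrophage list was not called, with a median of 0.03 (limma's camera, adjusted p = 0.925). Without control mouse 3 that list was called higher, with a median of 0.37 (limma's camera, adjusted p = 0.000117). Without control mouse 2 its median was -0.30 and it was not called (limma's camera, adjusted p = 0.0688).

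**Figure D2:**
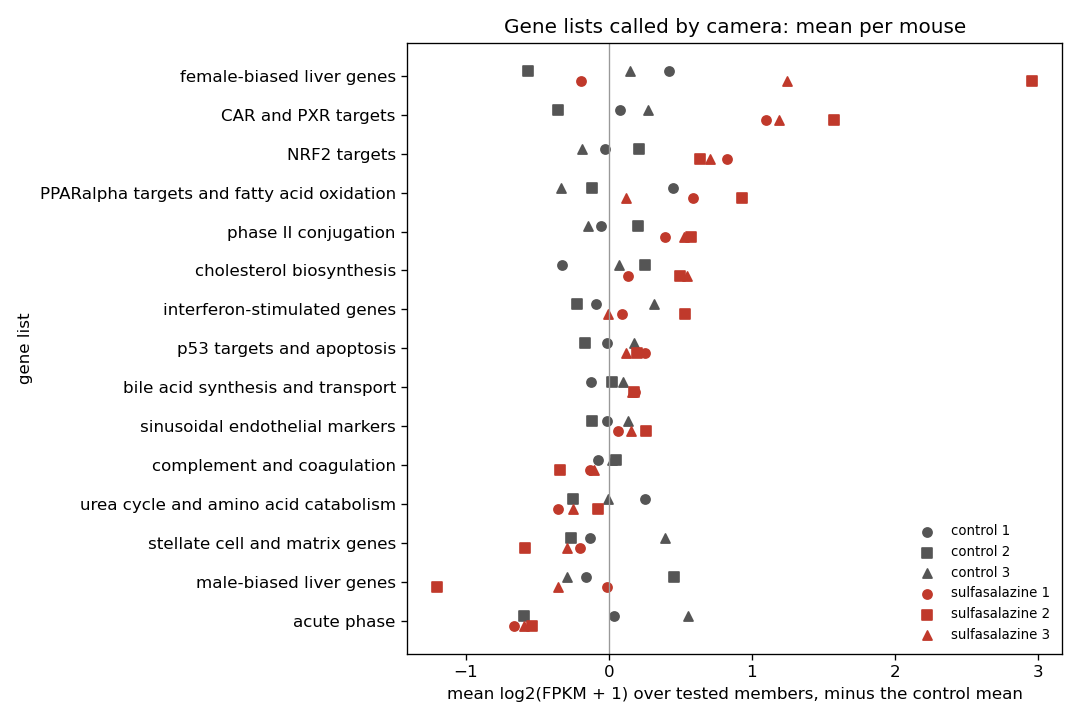
Mean log2(FPKM + 1) over the tested members of the 15 lists called by camera, per mouse, minus the mean of the control mice. Shapes mark the replicate numbers; treated mice are red and control mice grey. For CAR and PXR targets the treated mice lie at 1.10, 1.57 and 1.19, all above the control mice, while for female-biased genes sulfasalazine mouse 2 lies at 2.96 and sulfasalazine mouse 1 at -0.19.

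Male-biased genes were lower and female-biased genes higher as groups. The female-biased list shares Cyp2b9 and Cyp2a4, among others, with the CAR and PXR targets. The male-biased list shares C6 with the complement and coagulation list. The 15 tested male-biased genes had a median of -0.41 (limma's camera, adjusted p = 0.00263; adjusted p = 0.615 with an estimated correlation), and the 8 tested female-biased genes had a median of 1.57 (limma's camera, adjusted p = 0.0296; adjusted p = 0.615 with an estimated correlation). Mup7, a major urinary protein, was at 1655, 1721 and 858 FPKM in the control mice and at 973, 369 and 619 in the treated mice. Cyp2b9 was at 2.52, 1.86 and 12.9 FPKM in the control mice and at 5.89, 60.5 and 28.5 in the treated mice. Without sulfasalazine mouse 2, or without control mouse 2, neither list was called; female-biased genes were also not called without control mouse 3 or sulfasalazine mouse 3 (limma's camera, adjusted p up to 0.295 for male-biased and 0.259 for female-biased genes). Without sulfasalazine mouse 2 the medians were -0.13 over 15 male-biased and 1.23 over 4 female-biased genes, and without control mouse 2 they were -0.38 over 15 and 1.21 over 8. Over the 6 fits they lay between -0.74 and -0.13 for male-biased and between 0.94 and 2.34 for female-biased genes.

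The other 6 called lists had medians between -0.23 and 0.27. Higher were interferon-stimulated genes (median 0.27), p53 and apoptosis genes (0.13), bile acid genes (0.17) and sinusoidal endothelial markers (0.11); lower were urea cycle and amino acid genes (-0.23) and complement and coagulation genes (-0.11). By limma's camera their adjusted p lay between 0.019 and 0.040, and at 0.495 or 0.615 to 0.641 with an estimated correlation. With the filter applied again, bile acid genes lost the call without any 1 mouse, p53 genes without control mouse 2, and the other 4 lists without any of 3 mice each (limma's camera, adjusted p up to 0.495). With the tested loci kept, bile acid genes lost it without control mouse 1 and without sulfasalazine mouse 2 or 3. Over the 6 fits with the filter applied again, medians lay between 0.09 and 0.51 for interferon, 0.04 and 0.27 for p53, 0.09 and 0.18 for bile acid and 0.04 and 0.18 for endothelial genes. They lay between -0.35 and -0.08 for urea cycle genes and between -0.13 and -0.08 for complement genes. In these lists 0 genes passed; 2 p53 genes, 2 bile acid genes and 1 endothelial gene passed upward when adjusted over the list alone. Fas, a death receptor, had 2.99 ± 0.355 and 4.80 ± 0.417 FPKM, and Abcc3, a basolateral bile acid exporter, had 81.3 ± 7.82 and 130 ± 12.9. Abcc3 is also on the list of CAR and PXR targets. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 16.5 ± 18.2 and 28.6 ± 9.0 FPKM, a difference within the spread between mice.

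Genes fixed in advance for their link to the drug gave small values. Slc7a11, the cystine carrier that sulfasalazine blocks, stayed at or under 0.0131 FPKM in each library. Spr, the sepiapterin reductase that the drug also binds, had 4.29 ± 1.36 and 5.80 ± 2.45 FPKM, and Abcg2, a transporter of the drug, had 5.02 ± 0.270 and 5.16 ± 0.941. Nat2, an acetyltransferase, had 1.34 ± 1.70 and 2.37 ± 2.44 FPKM. Tnf and Il1b stayed at or under 1.80 FPKM. The NF-kB and cytokine list, with 8 of its 25 loci tested, had a median of 0.09 and was not called (limma's camera, adjusted p = 0.45). Tnf and Il1b fell below the filter, so this result does not cover them. The list for ferroptosis and cystine uptake was not called either, with a median of 0.15 (limma's camera, adjusted p = 0.45). It had 16 of 20 loci tested, Slc7a11 not among them.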

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

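The alternatives that keep only loci with an Ensembl transcript, drop loci at 0, sum FPKM per symbol, or keep the tested loci while a mouse is left out were chosen after seeing the data. The 2 loci called higher became 1 with a pseudocount of 0.1 or 0.01, 0 with no filter, 1 with a minimum of 0.1 FPKM and 6 with 5 FPKM, 23 without limma's trend, 9 over loci with an Ensembl transcript, 10 over those with no library at 0, and 6 with FPKM summed per symbol. The 0 loci called lower became 1, 22, 3 and 2 with the 5 FPKM minimum, without the trend, over annotated loci and over those with no 0. With an unadjusted p under 0.05 and at least a 2-fold change, 121 loci were higher and 122 lower. Leaving out 1 mouse gave 1 to 9 higher, 0 to 6 lower and 8 to 18 lists; 5 of the 15 called lists were called in all 6 fits. Camera with an estimated correlation called 0 lists and fry called 1, the CAR and PXR targets. Interferon-stimulated genes kept a median of 0.303 with the 5 FPKM minimum, while camera's direction turned. With the replicate number as a block, 0 loci were higher, 0 lower and 12 lists called. The same-numbered mice did not deviate together (correlations of 0.00967, -0.0668 and -0.0222). These values show no sign of pairing but cannot settle it, and the labels do not say whether the number pairs mice. Over the settings run, 17 values of named genes fell below the threshold, 47 passed it and 3520 kept their side. The cause of these shifts was not tested. Depth is unknown, so its limit on low genes cannot be given.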

Other observations

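The tests of paralogs and of unannotated or zero loci were chosen after the result was seen; those of scaling, sex and splits were set after a first look at gene and list values, before the tested values were computed. Single mice also stood apart in genes not given above. Control mouse 1 had 283 FPKM of Cyp1a1, the classical target of the aryl hydrocarbon receptor, against 0.548 or less in each of the other 5 mice. Its Cyp1a2 was 2356 FPKM against 195 to 380 in the others. Control mouse 3 had the highest values of 3 marker genes picked after the values were seen, with S100a9 at 10.99 FPKM against 0.939 or less, Saa3 at 18.0 against 0.949 or less, and Marco at 10.6 against 1.24 or less. In sulfasalazine mouse 2, Dbp, a clock output gene, was at 9.11 FPKM against 0.429 or less in the others. Across the groups, Cry1 had 4.53, 4.21 and 7.23 FPKM in control and 1.73, 1.49 and 2.33 in treated livers. Nr1d1 had 1.82, 5.03 and 0.700 FPKM in control and 7.60, 23.8 and 8.25 in treated livers. The circadian list as a whole was not called (limma's camera, adjusted p = 0.78). Of its 15 tested members 7 had positive and 8 negative fold changes, and 1 passed downward when adjusted over the list alone. Camera tests for a shift in 1 direction, so this result cannot exclude clock genes that change in both directions.

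Pathways from the table's own annotation column, tested after the data were seen, gave 8 of 161 higher and 0 lower by limma's camera, and 0 with an estimated correlation. Drug metabolism by cytochrome P450 led with a median of 0.16 over 48 loci (adjusted p = 1.04e-05; adjusted p = 0.273 with an estimated correlation). The proteasome, 31 loci with a median of 0.16, was also called (adjusted p = 0.000305; adjusted p = 0.994 with an estimated correlation).

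The higher xenobiotic lists were weighed against 2 technical explanations. Scaling between libraries would have brought the median of CAR and PXR targets to about 0 once corrected, but it stayed at 1.28 or above under median-of-ratios scaling and quantile normalization. The median log2 fold change of all tested loci was -0.00206 before rescaling, so a constant factor per library had little to correct. If reads had only moved between near-identical paralogs, family totals would not differ; the log2 ratio was 2.35 for Cyp2a, 2.02 for Cyp2b, 0.86 for Cyp2c and 1.79 for Gstm, the median of the 5 families. For Gsta it was 0.46 and the groups overlapped, so moved reads stay open there, and a response to the drug may account for the others only as a hypothesis found and tested on the same data. With 10 splits of the 6 mice a share under 0.05 cannot be reached. The real split called 15 lists, and those that mix treated and control mice called 0 to 10. The CAR and PXR list also passed in some mixed splits (limma's camera, adjusted p of 0.00338, 0.0123 and 0.0299).

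Sulfasalazine mouse 2 had some female-biased transcripts, picked after the values were seen, at levels above those of the other mice. Sult3a1 was at 29.1 FPKM against 0.539 or less, A1bg at 11.2 against 1.41 or less, and Cyp3a41a at 65.6 against 4.94 or less. Other members did not do so: Cyp2a4 was at 19.8 FPKM there and 21.7 in sulfasalazine mouse 3. Fmo2 was at 1.04 FPKM, within the range of the other mice. A female or partly female sample could have caused the high values, but the sex-linked genes argue against it. The sum of 4 Y-linked genes was 15.8 FPKM there, 1.29 times the lowest of the other 5, and the locus holding Xist and Gm27927 was at 0.0110 FPKM, the lowest of the 6 mice. A change in the growth hormone pattern that sets these genes was not tested and stays open.

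Few loci passed the threshold. Without the 2244 tested loci that have no annotated transcript or a library at 0, 12 loci passed, 10 higher, among them Cyp2c55, Gsta1, Gstm3 and a locus that pools Mettl7a1 and Mettl7a3, and 2 lower, Sik1 and Lsm10. Removing as many loci at random gave 0 to 11 in 100 draws, with a median of 7, also above the 2 loci of the full test. In the full test Gsta1, Gstm3 and the Mettl7a1 and Mettl7a3 locus lay just over the threshold (limma, adjusted p = 0.0524). The unannotated or zero loci may therefore account for only part of the low count, by a margin of 1 over the highest draw. As for the count itself, 9 of the 10 splits, the real one included, gave at least the 2 loci of the real one. The highest other gave 8. The number of called loci therefore did not set the real grouping apart from those that mix treated and control mice. These splits are also too few for a share under 0.05.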
